A study of Mus musculus with 12 samples.

How the data were processed

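RNA-seq was measured in 12 libraries of mouse oocytes, 2 for each of 6 groups. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, total RNA was extracted with the RNeasy Plus Micro kit, libraries were made with the NEBNext Single Cell/Low Input kit and paired reads of 150 bases were sequenced on a HiSeq 4000. The TPM values deposited by the authors come in 2 tables, one of 8 PRC2 libraries with 55385 gene models and one of 4 PRC1 libraries with 55401. Per the submitters' processing notes, Trim Galore 0.6.10, HISAT2, SAMtools, Subread 2.0.3 and RSEM 1.3.3 were used with GRCm38/mm10. Which tool gave the TPM values, whether strand was used and how reads that match several places were assigned are not given in the sources used here. Each column sums to 1000000 within rounding, so TPM keeps no depth, and no count test was possible. A fixed sum also means that a rise in a few abundant models lowers all others. The tables were treated as normalized separately, and tests were made only within a table.

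Gene classes came from GENCODE vM21 on GRCm38. Its gene coordinates were identical for 54851 of 55385 models in the PRC2 table and 54848 of 55401 in the PRC1 table.

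Genes with a TPM of at least 1 in at least 2 libraries of a table were tested, 14153 in the PRC2 table and 14941 in the PRC1 table. Values were taken as log2(TPM + 1) and fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend), with all groups of a table in one fit and no covariate. Adjusted p-values are Benjamini-Hochberg over the genes of a contrast, with a threshold of 0.05. The contrasts were cKO against control at each stage, the difference of these effects, growing against non-growing oocytes in PRC2 control and in PRC2 cKO, and PRC1 cKO against control. All limma tests were two-sided.

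Fixed gene lists, 34 in all, were written before the data were examined, and those with at least 3 tested members were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a contrast. No list passed in any contrast with the estimated correlation. Named genes were chosen by a rule fixed before the data were examined: Eed, Rnf2 and Ring1, the 8 largest rises and 8 largest falls among genes that passed, with a mean of at least 5 TPM in the higher group and no overlap between the groups' libraries, and up to 4 members of each list with the smallest p. Predicted gene models were left out, where fewer than 5 genes passed in a direction those of smallest p were added as not passing, and for the difference of effects 4 were taken in each direction. Overlaps of calls were tested with Fisher's exact test in R. Sequence matches were found with blastn 2.17.0, and other tests used scipy 1.17.1.

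The fit was tested on simulated values for the real genes. With 200 changed genes among 14153 in the PRC2 non-growing comparison, 55% of 2-fold and 87% of 4-fold changes were recovered. With 200 changed genes among 14941 in the PRC1 comparison, which has 4 libraries, none was recovered at 2-fold or 4-fold. With 6000 changed genes, 76.1% of 2-fold and 93.8% of 4-fold changes were recovered. The PRC1 fit thus finds changes when many genes change and has little power for a few. Recovery was not measured separately for genes of low TPM, whose changes are understated on the scale used. These rates may be too high for low genes and are not taken as rates for all tested genes.

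Alternatives were the pseudocount, the low-value filter, quantile and trimmed-mean scaling, eBayes without trend or robust, a replicate block, each library left out, a 2-fold minimum, and a fit of only the 2 groups compared. Scaling to nuclear protein-coding genes was added after the data were examined.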

Results

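RNA-seq libraries of mouse oocytes were compared, 12 in all, with 2 per group in 6 groups. Non-growing oocytes came from ovaries at postnatal day 6 (P6) and growing oocytes from ovaries at postnatal day 7 (P7). In the PRC2 series, control oocytes (Eed F/+; Ddx4-Cre) were compared with a conditional knockout (cKO, Eed F/-; Ddx4-Cre) at both stages, which gave 8 libraries in one table. Eed encodes a core subunit of Polycomb repressive complex 2, and Ddx4-Cre recombines in germ cells. In the PRC1 series, control and cKO growing oocytes at P7 gave 4 libraries in a second table. Both PRC1 genotypes carry a Ring1 deletion in the labels. The control is labelled Rnf2 F/+ with no Cre named, while the PRC1 cKO label names Ddx4-Cre. As labelled, Cre and the knockout therefore differ together in this comparison. Ring1 and Rnf2 encode the 2 alternative ubiquitin ligase subunits of Polycomb repressive complex 1. The cKO label repeats Ring1 for the floxed allele where Rnf2 may have been meant, so these libraries are called PRC1 cKO as labelled. The values are TPM, transcript abundances scaled to sum to 1000000 in each library, so sequencing depth is unknown and gives no interval for a single value. The labels do not say that the libraries of a group came from separate animals, and p-values then measure only the spread between these libraries. Levels are given as mean ± SD with n = 2 per group, and log2 fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. Folds of single genes are these changes as ratios of TPM + 1, so they can differ from ratios of the TPM values.

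The targeted genes were examined first. Eed (chromosome 7, 89954654 to 89980983, GRCm38) was at 89.7 ± 1.15 TPM in control and 11.2 ± 1.25 TPM in PRC2 cKO non-growing oocytes (SD, n = 2), a log2 fold change of -2.90 (SE 0.11, limma adjusted p = 0.000252). In growing oocytes it was at 61.4 ± 1.29 and 9.87 ± 0.325 TPM (SD, n = 2), a change of -2.52 (SE 0.11, limma adjusted p = 0.0014). Every PRC2 cKO library was below every PRC2 control library. Rnf2 (chromosome 1, 151458004 to 151500955) gave no call in PRC1 cKO, and its direction depended on the scaling. It was at 59.2 and 53.8 TPM in the PRC1 control libraries and at 87.8 and 61.4 TPM in the libraries labelled PRC1 cKO, a log2 fold change of 0.37 (SE 0.21, limma adjusted p = 0.197). The change was -0.242 after trimmed-mean scaling and 0.041 after quantile normalization (limma adjusted p = 0.326 and 0.881). A value per gene can keep reads from exons outside a floxed part, and that part is not given in the sources used here, so the Rnf2 total does not check the label. Ring1 (chromosome 17, 34020792 to 34024680) was listed at 0 in both PRC1 control libraries and at 0.01 and 0.02 TPM in the PRC1 cKO libraries. In the separately normalized PRC2 table Ring1 lay between 0.1 and 0.92 TPM. It was below the filter and was not tested.

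**Figure D1:**
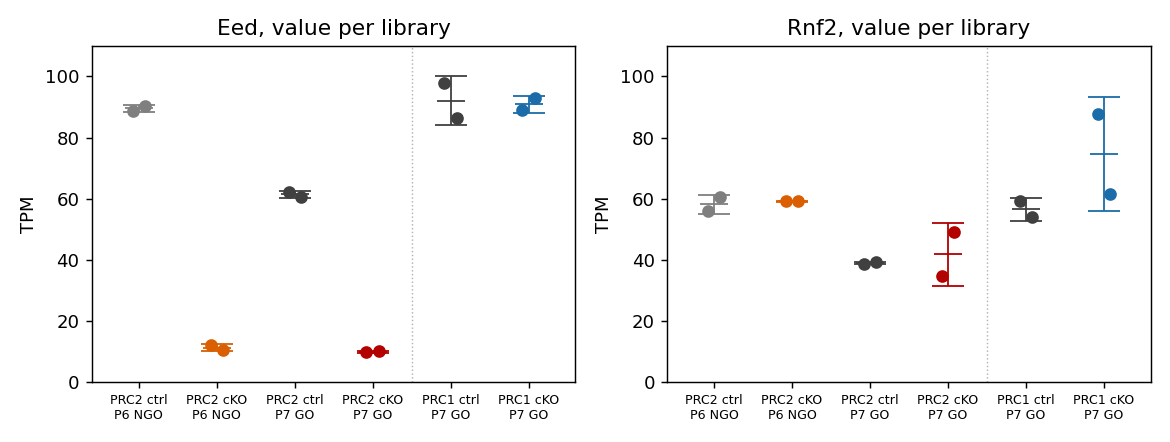
TPM of Eed (left) and Rnf2 (right) in each of the 12 libraries, with points for libraries and bars for mean and SD of 2 libraries. The dotted line separates the PRC2 table from the separately normalized PRC1 table. Eed lies between 9.64 and 12.1 TPM in the 4 PRC2 cKO libraries, while Rnf2 lies at 61.4 and 87.8 TPM in the PRC1 cKO libraries.

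The make-up of the libraries differed between stages. Gene models of the annotation class TEC, which still await experimental evidence, took 2.52 ± 0.064% of all TPM in control non-growing oocytes and 24.0 ± 0.17% in control growing oocytes of the PRC2 table (SD, n = 2). Their share was 21.7 ± 1.17% in PRC1 control and 12.96 ± 2.69% in PRC1 cKO growing oocytes. Protein-coding genes took 88.0 ± 0.346% of TPM in control non-growing and 61.9 ± 0.509% in control growing oocytes, and 62.0 ± 1.95% and 73.7 ± 3.35% in PRC1 control and PRC1 cKO. Gene models at 1 TPM or more numbered 12453 ± 197 in PRC1 control and 15261 ± 454 in PRC1 cKO libraries. Since TPM has a fixed sum, these shares move the value of every other gene.

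**Figure D2:**
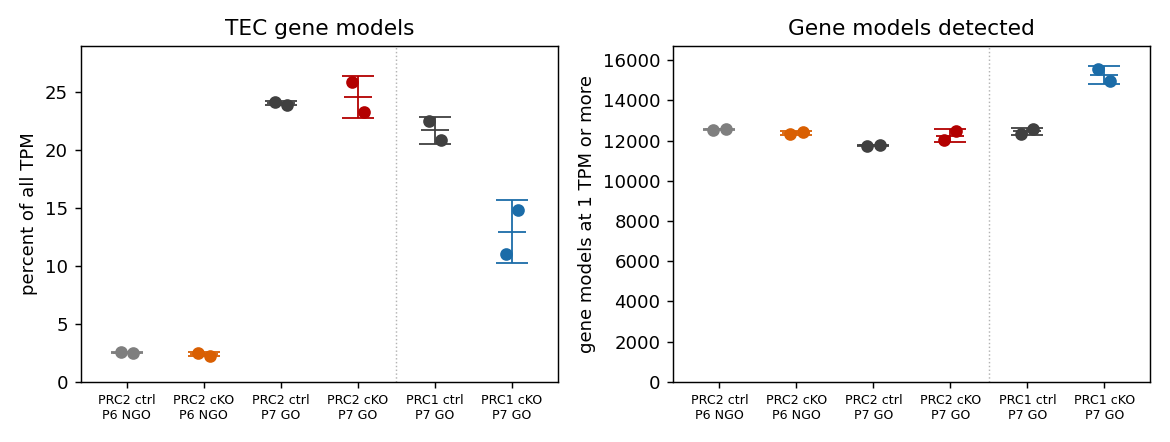
Percent of all TPM in TEC gene models (left) and number of gene models at 1 TPM or more (right) in each library, with points for libraries and bars for mean and SD of 2 libraries. TEC models hold 23.3 to 25.9% of TPM in the growing oocytes of the PRC2 table and 11.1 and 14.9% in the PRC1 cKO libraries.

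The series design asks how loss of PRC2 changes gene expression in non-growing oocytes. In PRC2 cKO non-growing oocytes, the X-linked gene Xlr3b rose from 101 ± 0.339 to 207 ± 7.25 TPM (log2 fold change 1.03, SE 0.09), Xlr3c from 24.7 ± 1.11 to 83.8 ± 16.1 TPM (1.71, SE 0.16) and the X-linked homeobox gene Rhox5 from 6.71 ± 0.545 to 22.6 ± 4.32 TPM (1.61, SE 0.20; SD, n = 2). Among the genes that fell were Gdpd3, a lysophospholipase D gene, from 92.3 ± 6.85 to 2.60 ± 1.79 TPM (-4.79, SE 0.39), and the histone gene H2bc4 from 43.2 ± 0.834 to 4.64 ± 0.693 TPM (-2.98, SE 0.15). Of 14153 genes tested with limma, 44 passed an adjusted p of 0.05, 16 higher and 28 lower, and 2316 had an unadjusted p under 0.05.

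The other named genes that rose were Rhox2d (3.37-fold), Rhox2b (2.58-fold), Tktl1, a transketolase-like gene (2.94-fold), the interferon-induced Ifitm2 (2.93-fold) and Nup62cl (2.03-fold). Of the 8 named genes that rose, all but Ifitm2 on chromosome 7 lie on the X chromosome. Further falls were seen for Galnt14, from 8.95 ± 1.32 to 0.435 ± 0.120 TPM, and the microfibril gene Mfap2, from 20.5 ± 1.32 to 4.76 ± 0.545 TPM. mt-Nd3, at 6.93 and 13.02 TPM in the controls, Slamf7, at 5.33 and 5.51 TPM, and Trav6d-3, at 4.48 and 6.35 TPM, were listed at 0 in both PRC2 cKO libraries, so that no fold is given. The other 12 mitochondrial mRNAs did not pass (median log2 fold change of all 13, 0.051), and with depth unknown a listed 0 does not show that mt-Nd3 RNA was absent. Rhox2 and Xlr3 genes have near-identical copies and H2bc4 belongs to a histone cluster, so how reads were split among copies is uncertain for them.

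In PRC2 cKO non-growing oocytes 7 fixed lists passed with the values as deposited, 3 with quantile normalization and 9 with trimmed-mean scaling. Of 43 tested maternal-effect genes, none passed over all genes, while 12 were lower and 1 higher adjusted over the list alone. The list as a whole stood below the other genes (camera adjusted p = 0.000213, adjusted p = 0.918 with an estimated correlation). Nlrp5, needed for cleavage of the early embryo, was at 2781 ± 30.8 TPM in control and 863 ± 23.5 TPM in cKO (limma adjusted p = 0.055, and from 0.00874 with quantile normalization to 0.335 over the alternatives). Ooep of the same subcortical complex was at 621 ± 4.38 and 451 ± 22.2 TPM (limma adjusted p = 0.102). Of 13 zona pellucida and secreted factor genes, 1 passed, Oosp1, which fell from 6.85 ± 0.735 to 2.06 ± 0.325 TPM, and 6 were lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0121, adjusted p = 0.918 with an estimated correlation, and 0.084 without PRC2 cKO non-growing replicate 1). Zp3 was at 2286 ± 42.4 and 1353 ± 3.70 TPM (limma adjusted p = 0.0585, and from 0.0135 with quantile normalization to 0.347 over the alternatives) and Gdf9 at 616 ± 28.8 and 399 ± 30.6 TPM (limma adjusted p = 0.113). Meiotic prophase genes stood above the other genes (camera adjusted p = 0.000213, adjusted p = 0.213 with an estimated correlation), with none of 42 passing over all genes and 3 higher and 1 lower adjusted over the list alone. Hormad1, a chromosome axis protein, was at 20.6 ± 0.460 and 40.5 ± 0.926 TPM (limma adjusted p = 0.0901). Among 38 replication-dependent histone genes, H2bc4 passed, with 6 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.185). H1f2 was at 12.97 ± 3.17 and 2.35 ± 0.622 TPM (limma adjusted p = 0.055, and from 0.033 with a pseudocount of 5 to 0.347 over the alternatives). The lists of granulosa, stromal, endothelial and immune cell markers did not pass (camera adjusted p = 0.408, 0.8, 0.935 and 0.716). Of 14 immediate-early and heat shock genes, which respond to handling, none passed over all genes and 1 was higher adjusted over the list alone. The list stood above the other genes with a median of 0.203 (camera adjusted p = 0.0326, adjusted p = 0.918 with an estimated correlation, and 0.0875 without PRC2 control or 0.748 without PRC2 cKO non-growing replicate 2). Cytosolic ribosomal protein, nuclear oxidative phosphorylation and proteasome genes stood above the other genes by small amounts, with medians of 0.054, 0.072 and 0.032 and no member passing. These lists lost their call with an estimated correlation and without PRC2 cKO non-growing replicate 1 (camera adjusted p = 0.00444, 0.00321 and 0.0453, each 0.918 with an estimated correlation, and 0.176, 0.174 and 0.174 without PRC2 cKO non-growing replicate 1). The proteasome list also did not pass without PRC2 control non-growing replicate 1 (camera adjusted p = 0.16), PRC2 cKO non-growing replicate 2 (0.0818) or either PRC2 control growing library (0.0557).

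The excess of lower calls turned with a pseudocount of 5 (47 higher and 40 lower) and without the filter (47 and 44). It stayed with the other alternatives that left no library out. When only the 2 groups compared were fitted 10 genes passed, and 29 passed after trimmed-mean scaling. With 1 library left out the count was 23 and 14 without either PRC2 control non-growing library, 27 without PRC2 cKO non-growing replicate 2 and 27 without either PRC2 control growing library. Of 17 named genes that passed, 13 kept their call with trimmed-mean scaling, 14 with quantile normalization and 4 with every library left out in turn, namely Eed, H2bc4, Galnt14 and Slamf7. With each of the 8 libraries left out in turn, the call was lost in 8 for Rhox5 and Nup62cl, 7 for Ifitm2, 6 for Rhox2b, Rhox2d, Tktl1, mt-Nd3, Oosp1 and Trav6d-3, 4 for Xlr3b and Mfap2 and 2 for Xlr3c and Gdpd3. Trimmed-mean scaling ended the calls of Oosp1, Trav6d-3, Ifitm2 and Nup62cl.

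In PRC2 cKO growing oocytes, the co-stimulatory receptor gene Cd40 rose from 0.285 ± 0.191 to 5.56 ± 0.120 TPM (log2 fold change 2.36, SE 0.17). The X-linked gene Mageb4 rose from 8.59 ± 2.91 to 36.6 ± 4.55 TPM (2.00, SE 0.21), and Xlr3b from 29.8 ± 2.49 to 56.7 ± 1.37 TPM (0.91, SE 0.09; SD, n = 2). Spata21 fell from 21.6 ± 0.799 to 4.22 ± 0.743 TPM (-2.12, SE 0.17). With limma, 24 of 14153 genes passed an adjusted p of 0.05, 17 higher and 7 lower, and 1407 had an unadjusted p under 0.05. After trimmed-mean scaling 11 were higher and 8 lower.

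Rsph3b (3.5-fold), Rhox2b (2.52-fold) and Pdpn (2.19-fold) also rose. The microRNA locus Mir7035 was listed at 0 in the other 6 libraries of the table and at 454 and 181 TPM in the PRC2 cKO growing libraries. mt-Nd3 was listed at 0 in both control growing libraries and at 6.93 and 14.7 TPM in the cKO, opposite to its direction in non-growing oocytes, while the other 12 mitochondrial mRNAs did not pass here either (median log2 fold change of all 13, 0.033). The call of mt-Nd3 was lost with 7 of the 8 libraries left out in turn. Among genes that did not pass, Rln3 was at 322 ± 6.10 TPM in control and 167 ± 17.4 TPM in cKO (limma adjusted p = 0.087), the oocyte homeobox gene Obox5 at 224 ± 2.45 and 128 ± 8.42 TPM (limma adjusted p = 0.101, and from 0.0432 with trimmed-mean scaling to 0.411 over the alternatives) and Gdpd3 at 19.2 ± 0.198 and 3.31 ± 1.70 TPM (limma adjusted p = 0.139).

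Of 42 meiotic prophase genes, 2 were higher and none lower, with 6 higher adjusted over the list alone (camera adjusted p = 0.00159, adjusted p = 0.373 with an estimated correlation, and 0.125 without PRC2 cKO growing replicate 1). They were Sycp3, of the synaptonemal complex, from 353 ± 12.6 to 579 ± 62.6 TPM, and Mael, of the piRNA pathway, from 89.4 ± 1.29 to 164 ± 11.7 TPM. The call of Sycp3 was lost with trimmed-mean scaling (limma adjusted p = 0.254, from 0.034 to 0.574 over the alternatives) and with quantile normalization (0.0622), and the calls of both genes with 7 of the 8 libraries left out in turn. Of 14 noncanonically imprinted genes, which are silenced by maternal H3K27me3 in early embryos, none passed and 4 were higher adjusted over the list alone (camera adjusted p = 0.00049, adjusted p = 0.669 with an estimated correlation). Slc38a1 was at 5.72 ± 0.898 and 17.4 ± 4.58 TPM (limma adjusted p = 0.101). Of 16 primordial oocyte factors, none passed and 4 were higher adjusted over the list alone (camera adjusted p = 0.0105, adjusted p = 0.669 with an estimated correlation, and 0.0876 without PRC2 control or 0.0897 without PRC2 cKO growing replicate 2). Sohlh1 was at 50.2 ± 21.4 and 111 ± 21.3 TPM (limma adjusted p = 0.298). Cytosolic ribosomal protein genes stood below the other genes by a small amount, with a median log2 fold change of -0.07 against 0.08 for all genes and none of 85 passing over all genes or adjusted over the list alone (camera adjusted p = 3.04e-06, adjusted p = 0.669 with an estimated correlation). That difference was 0.002 in the other direction without PRC2 cKO growing replicate 2 and did not pass without PRC2 control growing replicate 1 (camera adjusted p = 0.437). Of the marker lists of other cells, the 3 tested immune genes stood below the other genes, with a median of -0.614. None passed over all genes and 2 were lower adjusted over the list alone (camera adjusted p = 0.00393, adjusted p = 0.669 with an estimated correlation, and 0.121 without the filter). The granulosa, stromal and endothelial lists did not pass (camera adjusted p = 0.529, 0.421 and 0.994). Among other lists, PRC2 subunits passed, with the targeted Eed the 1 of 10 to pass (camera adjusted p = 0.00406). That list holds Eed, so the knockout set part of its direction, and it was not tested without Eed. Maternal-effect (camera adjusted p = 0.0419), mitochondrial ribosomal protein (0.00445) and nuclear oxidative phosphorylation genes (0.00159) also passed, like PRC2 subunits below the other genes. The piRNA pathway genes stood above them, with Mael the 1 of 23 to pass (camera adjusted p = 0.0117). None passed with an estimated correlation (adjusted p = 0.669 to 0.753), and each was lost without at least 1 library. PRC2 subunits were lost without PRC2 control growing replicate 2 (0.0768) or PRC2 cKO growing replicate 1 (camera adjusted p = 0.298). Maternal-effect genes were lost without the same libraries (0.361 and 0.806) or either PRC2 control non-growing library (0.0516 and 0.0506). The piRNA genes were lost without PRC2 control (0.0768) or PRC2 cKO growing replicate 2 (0.127). Mitochondrial ribosomal protein and oxidative phosphorylation genes were lost without PRC2 control growing replicate 1 (0.524 and 0.658) or PRC2 cKO growing replicate 2 (0.971 and 0.0884).

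A single gene, higher in the cKO, passed when only the 2 groups compared were fitted, and the count was 10 without either PRC2 control non-growing library and 13 without either PRC2 cKO non-growing library. Of 12 named genes that passed, 7 kept their call with trimmed-mean scaling, 8 with quantile normalization and 3 with every library left out in turn, namely Eed, Mir7035 and Cd40. Trimmed-mean scaling ended the calls of Mageb4, Xlr3b, Rhox2b, Rsph3b and Sycp3.

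The PRC2 cKO effect was compared between the stages as an interaction. H2bc4 was lower in PRC2 cKO non-growing oocytes, and in growing oocytes it was at 59.3 and 47.2 TPM in control and 51.4 and 55.7 TPM in cKO (difference of log2 fold changes 2.99, SE 0.21, limma adjusted p = 0.0102). The differences also passed for Slamf7 (limma adjusted p = 0.0325), for mt-Nd3 (limma adjusted p = 0.0148), the only 1 of 13 mitochondrial mRNAs to pass, and for Mir7035 (limma adjusted p = 0.00934). These 3 were listed at 0 in both libraries of at least 1 group, where the pseudocount sets the size of the difference, so that no size is given. None of these 4 calls was kept with every library left out. Of 8 left out in turn, 7 ended the call of Slamf7, 4 that of mt-Nd3, 4 that of Mir7035 and 2 that of H2bc4. Trimmed-mean scaling ended that of Slamf7 (limma adjusted p = 0.0708, and up to 0.21 over the alternatives). The reduction of Eed did not differ by this test (0.38, SE 0.16, limma adjusted p = 0.319). In all, 14 genes passed, 13 with a higher effect in growing oocytes, and 2230 had an unadjusted p under 0.05. Ifitm2 (-1.77, limma adjusted p = 0.197) and the chromatin remodeller Smarca2 (-0.62, limma adjusted p = 0.257) had the opposite direction without passing. Across the 14153 genes, the PRC2 cKO effects at the 2 stages had a Pearson correlation of -0.01 and a Spearman correlation of -0.13, and genes are not independent replicates. Of the calls, 2 genes were higher at both stages (two-sided Fisher's exact test p = 0.000161) and 3 were lower at both, the targeted Eed among them (p = 2.41e-07 by the same exact test). In the opposite sense, 1 gene, mt-Nd3, was lower in non-growing and higher in growing oocytes (p = 0.0331 by the same exact test), and none was higher in non-growing and lower in growing oocytes. Both effects share an estimate of the spread of each gene and Eed was targeted at both stages. The calls are therefore not independent, and these exact tests can overstate the overlap. Of the fixed lists, cytosolic ribosomal protein (camera adjusted p = 7.12e-08), nuclear oxidative phosphorylation (6.46e-06), mitochondrial ribosomal protein (0.0106) and proteasome genes (0.0268) stood below the other genes in this difference. Their medians were -0.159, -0.134, -0.072 and -0.057, and no member passed. None of the 4 passed with an estimated correlation (adjusted p = 0.826) or without PRC2 cKO growing replicate 2 (camera adjusted p = 0.0744, 0.178, 0.237 and 0.178). Mitochondrial ribosomal protein and proteasome genes also did not pass without PRC2 cKO non-growing replicate 1 (0.0704 and 0.0589) or PRC2 control growing replicate 1 (0.292 and 0.0617), nor proteasome genes without PRC2 control non-growing replicate 1 (0.0719). The count of genes was 842 without PRC2 cKO growing replicate 1, and 3 and 5 without PRC2 cKO non-growing replicate 1 or 2 and 5 and 7 without PRC2 control growing replicate 1 or 2.

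Growing were compared with non-growing oocytes within the PRC2 controls, where stage and age differ together. As lists, oocyte-secreted and maternal-effect genes stood above the other genes in growing oocytes, and ribosomal protein and respiratory chain genes stood below them, with the preset correlation and not with an estimated one (adjusted p = 0.309, 0.435, 0.568 and 0.54). Bmp15, a growth factor that acts on granulosa cells, rose from 14.1 ± 0.290 to 411 ± 68.8 TPM (log2 fold change 4.76, SE 0.19), and Oosp1 from 6.85 ± 0.735 to 298 ± 50.4 TPM (5.24, SE 0.15; SD, n = 2). The meiotic gene Sycp3 fell from 3378 ± 20.3 to 353 ± 12.6 TPM (-3.26, SE 0.09). With limma, 9986 of 14153 genes passed, 2346 higher and 7640 lower.

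All fold changes had a median of -0.67, and trimmed-mean scaling brought it to -0.07 and the calls to 4045 higher and 4115 lower. Scaling to protein-coding genes, chosen after seeing the data, gave 3302 higher and 5480 lower, and quantile normalization 3520 and 5116. Of 13 zona and secreted factor genes, 11 were higher and none lower (camera adjusted p = 1.69e-09, adjusted p = 0.309 with an estimated correlation), with a median 3.15 above that of all genes. Of 43 maternal-effect genes, 29 were higher and 6 lower (camera adjusted p = 5.09e-12, adjusted p = 0.435 with an estimated correlation). Among them the histone chaperone gene Npm2 rose from 165 ± 9.80 to 1365 ± 54.7 TPM, Nlrp2 from 2.17 ± 0.170 to 122 ± 27.3 TPM and Bcl2l10 from 81.1 ± 6.58 to 1112 ± 110 TPM. All 5 tested genes of the embryonic cleavage-stage list were higher (camera adjusted p = 6.89e-06, adjusted p = 0.309 with an estimated correlation), including Tcstv1, from 0.39 ± 0.113 to 58.7 ± 5.01 TPM. Genes silent in non-growing oocytes met the filter on low values only through growing libraries, which raises this share. Without the filter 6 of 23 were higher and none lower, with a median of 0.084 against -0.061 for all genes. On the log2(TPM + 1) scale, the largest rises of named genes included the F-box genes Fbxw20 (155-fold), Fbxw14 (141-fold), Fbxw28 (137-fold) and Fbxw16 (100.4-fold). The homeobox genes Obox1 (114-fold), Obox5 (95.7-fold) and Obox2 (84.0-fold) and the antithrombin gene Serpinc1 (111-fold) were also among them. The Fbxw and Obox genes are clusters of near-identical copies, and their values depend on how reads were split.

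Of 42 meiotic prophase genes, 1 was higher and 30 lower, and the list as a whole did not pass (camera adjusted p = 0.0619, and 0.0279 without PRC2 control non-growing replicate 2 and 0.0368 and 0.0305 without PRC2 control growing replicate 1 or 2), or 8 higher and 23 lower after trimmed-mean scaling. Syce1 fell from 467 ± 1.10 to 36.4 ± 3.22 TPM. Of 85 cytosolic ribosomal protein genes, 82 were lower and 1 higher (camera adjusted p = 9.91e-11, adjusted p = 0.568 with an estimated correlation), a median 0.99 below that of all genes, and 62 were lower after trimmed-mean scaling. Rpl4 fell from 1491 ± 45.2 to 305 ± 24.7 TPM. Of 82 nuclear genes of oxidative phosphorylation, 81 were lower (camera adjusted p = 5.08e-10, adjusted p = 0.54 with an estimated correlation) and 47 after trimmed-mean scaling. The primordial oocyte factors Figla, from 979 ± 18.4 to 332 ± 42.7 TPM, and Sohlh1, from 347 ± 17.2 to 50.2 ± 21.4 TPM, also fell. Of the 16 on that list 12 were lower and 1 higher (camera adjusted p = 0.301), or 5 lower and 4 higher after trimmed-mean scaling. Adjusted over the list alone, the counts were 11 higher for the zona list, 29 higher and 6 lower for the maternal-effect list, 5 higher for the cleavage-stage list, 2 higher and 30 lower for the meiotic list, 1 higher and 82 lower for ribosomal proteins, 81 lower for oxidative phosphorylation and 1 higher and 13 lower for the primordial list. Mitochondrial ribosomal protein (71 of 77) and proteasome genes (32 of 37) were also lower (camera adjusted p = 1.57e-07 and 0.000582, 0.443 and 0.309 with an estimated correlation). The 16 pluripotency and early germ cell genes passed as a list above the other genes with 6 higher and 6 lower (camera adjusted p = 0.0218, 0.46 with an estimated correlation). The stress gene Nupr1 fell from 117 ± 4.77 to 1.07 ± 0.757 TPM and the cell cycle inhibitor gene Cdkn1a from 78.3 ± 1.29 to 7.26 ± 3.18 TPM. Large falls were also seen for the histone genes Hist1h2ao (112-fold) and Hist1h2ap (44.6-fold), which have near-identical copies. Pcgf1, a PRC1 subunit gene, rose from 61.0 ± 1.64 to 574 ± 51.3 TPM and Ezh2, the PRC2 methyltransferase gene, from 74.9 ± 4.77 to 152 ± 4.94 TPM. The lower values of Eed (-0.54) and Rnf2 (-0.57) turned to 0.22 and 0.19 after trimmed-mean scaling, where neither passed.

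Growth in the PRC2 cKO oocytes gave 9360 calls with limma, 2844 higher and 6516 lower, or 4231 higher and 4436 lower after trimmed-mean scaling, 3646 and 5371 after quantile normalization and 4074 and 4570 with scaling to protein-coding genes. Fbxw28 rose 297-fold, Fbxw20 242-fold and the phospholipase gene Plcb1 from 1.59 ± 1.28 to 478 ± 32.6 TPM (SD, n = 2). Selenop, a selenium transport gene, fell from 257 ± 38.9 to 8.68 ± 0.184 TPM and the transcriptional regulator gene Id1 from 377 ± 211 to 15.6 ± 0.163 TPM. Of the 13 zona and secreted genes 12 were higher (camera adjusted p = 9.76e-09, adjusted p = 0.233 with an estimated correlation), and of the 42 meiotic prophase genes 29 were lower and 2 higher (camera adjusted p = 0.0091, adjusted p = 0.233 with an estimated correlation). The growth effects in cKO and control had a Pearson correlation of 0.90 across genes. They shared 2114 higher calls, against 471 for independent lists, and 6014 lower calls, against 3517.

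**Figure D3:**
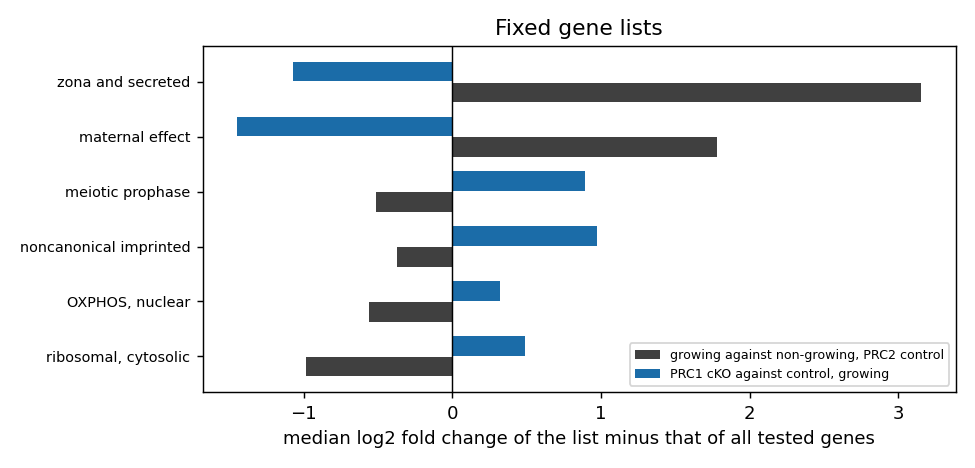
Median log2 fold change of the tested genes of 6 fixed lists minus the median of all tested genes, for growing against non-growing PRC2 control oocytes (grey) and for PRC1 cKO against control growing oocytes (blue). Zona and secreted genes lie at 3.15 and -1.07 and maternal-effect genes at 1.78 and -1.45, and the other 4 lists lie below 0 with growth and above 0 in PRC1 cKO.

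The second question of the series design is how loss of PRC1 changes gene expression in growing oocytes. In the libraries labelled PRC1 cKO, oocyte-secreted and maternal-effect genes stood below the other genes as lists, and meiotic and noncanonically imprinted genes stood above them, with part of the members of each not passing. These lists passed with the preset correlation and not with an estimated one (adjusted p = 0.512, 0.512, 0.757 and 0.757). Bmp15 fell from 401 ± 65.9 to 48.2 ± 36.9 TPM (log2 fold change -3.26, SE 0.56) and Gdf9 from 5044 ± 255 to 1889 ± 448 TPM (-1.44, SE 0.20; SD, n = 2). Sycp1, the transverse filament of the synaptonemal complex, rose from 44.6 ± 4.75 to 392 ± 82.5 TPM (3.09, SE 0.19), and the homeobox gene Lmx1a from 0.145 ± 0.035 to 20.4 ± 0.7 TPM (4.22, SE 0.21). With limma, 7140 of 14941 genes passed an adjusted p of 0.05, 6176 higher and 964 lower.

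The median of all fold changes was 0.55. After trimmed-mean scaling it was 0.02 and the calls were 3488 higher and 2946 lower, after quantile normalization they were 2722 and 2636, and after scaling to protein-coding genes, chosen after seeing the data, 5052 and 1512. Of 43 maternal-effect genes, 24 were lower and 3 higher (camera adjusted p = 6.61e-17, adjusted p = 0.512 with an estimated correlation), or 27 lower and 3 higher adjusted over the list alone and 31 lower after trimmed-mean scaling. Btg4, an mRNA deadenylation adaptor, fell from 611 ± 50.6 to 158 ± 10.3 TPM, and Zfp57, which maintains imprints, from 932 ± 5.73 to 459 ± 31.9 TPM. Patl2 fell from 149 ± 14.7 to 39.7 ± 9.07 TPM. Of 13 zona and secreted genes, 6 were lower and 1 higher (camera adjusted p = 1.86e-07, adjusted p = 0.512 with an estimated correlation), and 12 were lower after trimmed-mean scaling. Fgf8 fell from 105 ± 2.86 to 12.3 ± 9.72 TPM and Oosp1 from 307 ± 14.9 to 53.7 ± 18.3 TPM. Further falls were seen for Obox2 (32.0-fold), Obox1 (19.2-fold), Obox5 (8.73-fold) and Cyp2c29 (8.75-fold).

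Of 42 meiotic prophase genes, 33 were higher and none lower (camera adjusted p = 0.00301, adjusted p = 0.757 with an estimated correlation), or 23 higher and 6 lower after trimmed-mean scaling. Spata22 rose from 0.82 ± 0.057 to 34.4 ± 1.90 TPM, Syce3 from 1.21 ± 0.269 to 28.1 ± 3.55 TPM and Syce1 from 52.8 ± 9.43 to 290 ± 11.4 TPM. The filter on low values was met by genes silent in the controls only if they rose in cKO, so it raises the share of higher genes in lists of mostly silent genes. Of 9 Hox genes above the filter, 8 were higher (camera adjusted p = 0.0115, adjusted p = 0.757 with an estimated correlation) and 3 after quantile normalization, all at low levels, such as Hoxd8 at 3.14 ± 0.778 TPM in cKO. Of 46 other developmental regulators above the filter, 30 were higher and 1 lower (camera adjusted p = 0.0202, adjusted p = 0.757 with an estimated correlation), or 13 and 7 after quantile normalization. Lhx6 rose from 0.75 ± 0.424 to 23.3 ± 2.98 TPM. Without the filter 11 of 33 Hox genes and 47 of 159 developmental regulators were higher and none lower. Their medians were 0.112 and 0.201 against 0.149 for all genes (camera adjusted p = 0.0434 and 0.00861). With a minimum of 5 TPM the developmental regulators did not pass (camera adjusted p = 0.39). Of 17 noncanonically imprinted genes, 14 were higher and none lower (camera adjusted p = 0.011, adjusted p = 0.757 with an estimated correlation), and Clic6 rose from 0.26 ± 0.028 to 14.2 ± 4.95 TPM. Of 86 cytosolic ribosomal protein genes, 79 were higher (camera adjusted p = 1.86e-07, adjusted p = 0.757 with an estimated correlation), a median 0.49 above that of all genes, and 32 after trimmed-mean scaling. Rps27 rose from 281 ± 37.9 to 1192 ± 85.0 TPM. Of 83 nuclear genes of oxidative phosphorylation, 70 were higher (camera adjusted p = 5.02e-07, adjusted p = 0.757 with an estimated correlation) and 19 after trimmed-mean scaling. Lists that stood below the other genes, with members passing in both directions, were cytoskeletal (camera adjusted p = 0.011), replication-dependent histone (0.011), histone modifier (0.025), PRC2 subunit (0.03) and PRC1 subunit genes (0.0487). With an estimated correlation each had an adjusted p of 0.757. The histone list did not pass without PRC1 cKO replicate 1 (camera adjusted p = 0.0647). The other 4 did not pass without PRC1 cKO replicate 2 (0.0508, 0.126, 0.0508 and 0.242), nor PRC1 subunits without PRC1 control replicate 2 (0.0915). Adjusted over the list alone, the counts were 1 higher and 6 lower for the zona list, 33 higher for the meiotic list, 8 for Hox genes, 34 higher and 2 lower for developmental regulators, 15 higher for noncanonically imprinted genes, 80 for ribosomal proteins and 77 for oxidative phosphorylation.

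Among the largest rises were the cleavage-stage genes Usp17le (61.3-fold) and Zscan4f (53.6-fold), both from families of near-identical copies, with 12 of 16 tested genes of that list higher and 2 lower, over all genes and adjusted over the list alone (camera adjusted p = 0.0886, and 0.0131 and 0.0435 without PRC1 control replicate 1 or 2 and 0.0077 without PRC1 cKO replicate 1). Without the filter 12 of 26 genes of that list were higher and 1 lower. Igfbp2, an insulin-like growth factor binding protein gene, rose from 0.33 ± 0.212 to 71.8 ± 11.3 TPM, the glucocorticoid-induced gene Tsc22d3 from 2.75 ± 1.32 to 165 ± 22.9 TPM, the X-linked homeobox gene Rhox6 from 0.49 ± 0.085 to 62.6 ± 8.51 TPM, the lactate dehydrogenase gene Ldha from 1.38 ± 0.467 to 102 ± 36.4 TPM and the imprinted gene Dlk1 from 2.74 ± 0.877 to 157 ± 44.2 TPM. Of 16 primordial oocyte factors, 9 were higher and 1 lower (camera adjusted p = 0.613), or 3 and 3 after trimmed-mean scaling, and Sohlh1 rose from 124 ± 47.5 to 792 ± 275 TPM. Eed was at 92.1 ± 8.004 and 90.9 ± 2.72 TPM (log2 fold change -0.016, limma adjusted p = 0.933). After trimmed-mean scaling its change was -0.634 and passed (limma adjusted p = 0.0366, and up to 0.962 over the alternatives). Some markers of other ovarian cells were higher, while their lists did not pass: 11 of 15 granulosa cell markers (camera adjusted p = 0.37), 3 of 4 stromal markers (camera adjusted p = 0.261) and 6 of 8 endothelial markers (camera adjusted p = 0.39) were higher, at low levels such as Inhba at 2.93 ± 0.948 TPM and Tie1 at 4.37 ± 0.955 TPM in cKO. The filter raises these shares too. Without it 11 of 31, 5 of 23 and 4 of 14 were higher and none lower, against 5754 of all 32244 genes higher. Of 9 abundant somatic transcripts, Amh, Foxl2, Col1a1, Col1a2, Col3a1 and Ptprc stayed below 1 TPM in both cKO libraries. Dcn and Lum reached 2.09 and 1.08 TPM in cKO replicate 2, and Pecam1 was at 2.32 and 5.73 TPM against 5.62 and 3.72 TPM in the controls. Col1a1, Col3a1, Dcn, Foxl2, Lum and Ptprc were higher in both cKO libraries than in both controls. Col1a1, for example, was at 0.27 and 0.23 TPM against 0.01 and 0.03 TPM. Amh and Col1a2, like Pecam1, overlapped between the groups.

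**Figure D4:**
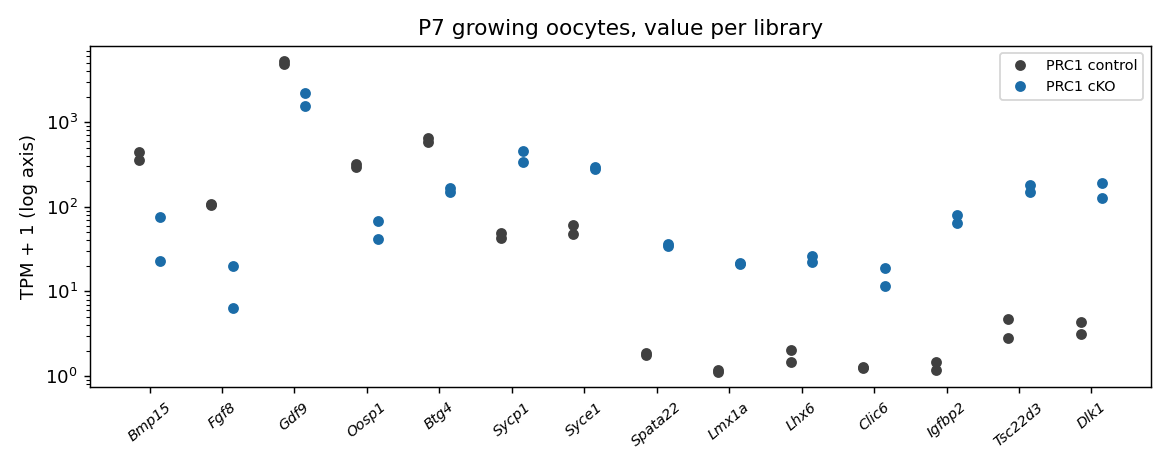
TPM + 1 on a log axis for 14 named genes in P7 growing oocytes, with one point per library for PRC1 control (dark grey) and PRC1 cKO (blue). Bmp15, Fgf8, Gdf9, Oosp1 and Btg4 are lower in both cKO libraries than in both controls, and the other 9 genes are higher.

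With 1 library left out, the count of calls was 2953 and 4223 without PRC1 control replicate 1 or 2 and 4400 without PRC1 cKO replicate 1. Of 49 named genes that passed, 44 kept their call with each library left out in turn; Ezh2, Mir719, Obox1, Obox5 and Scml2 did not.

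The genes called in the PRC2 table were then tested as lists in the PRC1 libraries, which share no library with them. Of 2244 tested genes that rose with growth, 665 were lower and 256 higher in PRC1 cKO (camera adjusted p = 2.48e-46, adjusted p = 0.111 with an estimated correlation). Independent lists would share 157.7 and 834.8. Of 7155 tested genes that fell with growth, 3846 were higher and 55 lower in PRC1 cKO (camera adjusted p = 9.61e-14, adjusted p = 0.325 with an estimated correlation). Here independent lists would share 2661.8 and 502.9, since higher calls were common among all genes. The PRC1 cKO effect and the growth effect had a Pearson correlation of -0.56 and a Spearman correlation of -0.57 across 13147 genes, which are not independent replicates. Of 11 tested genes higher in PRC2 cKO non-growing oocytes, 10 were higher in PRC1 cKO (camera adjusted p = 0.000164, adjusted p = 0.111 with an estimated correlation; two-sided Fisher's exact test p = 0.000368). Of 21 genes lower in PRC2 cKO non-growing oocytes, 9 were lower and 3 higher in PRC1 cKO (camera adjusted p = 3.76e-06, adjusted p = 0.111 with an estimated correlation; two-sided Fisher's exact test p = 5.47e-06). In growing oocytes, 7 of 11 genes higher in PRC2 cKO were higher in PRC1 cKO, where independent lists share 4.1 (two-sided Fisher's exact test p = 0.114), and 1 of 7 lower genes was lower in both (p = 0.4 by the same exact test). As a list, these 7 lower genes stood below the other genes in PRC1 cKO (camera adjusted p = 0.0305, adjusted p = 0.222 with an estimated correlation). The 11 higher genes did not pass as a list (camera adjusted p = 0.0745). The overlap of higher genes passed without PRC1 control replicate 1 (p = 0.000198) or 2 (p = 0.000383) and without PRC1 cKO replicate 1 (p = 0.00238) or 2 (p = 0.0455, exact tests), and no higher gene was shared without any 1 of the 4 non-growing libraries. The PRC1 and PRC2 cKO effects in growing oocytes had a Pearson correlation of 0.16 across genes. Among the 500 genes of smallest p per direction, 80 higher genes were shared, where independent lists share 19 (two-sided Fisher's exact test p = 6.3e-29).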

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

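The tests below of somatic RNA and of the share of TEC, lincRNA and miRNA models in PRC1 cKO were chosen after the result was seen.

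The PRC2 cKO effect differed between growing and non-growing oocytes for 14 genes by the interaction test of limma. The named ones were Mir7035 (8.17), mt-Nd3 (6.88), H2bc4 (2.99) and Slamf7 (2.68), as differences on the log2(TPM + 1) scale, where those of Mir7035, mt-Nd3 and Slamf7 are set by the pseudocount, since whole groups were listed at 0, and 8 of the 14 are microRNA models, Mir7035 among them, and 1 is an antisense model. None of the 4 calls was kept with every library left out: of 8 left out in turn, 7 ended the call of Slamf7, 4 that of mt-Nd3, 4 that of Mir7035 and 2 that of H2bc4. The other 12 mitochondrial mRNAs did not pass, and mt-Nd3 was listed at 0 in 4 of the 8 libraries. No explanation was tested for them.

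Called genes in PRC1 cKO growing oocytes were mostly higher. A common factor on every gene cannot be told apart from other causes: trimmed-mean scaling took the higher share of calls from 86.5% to 54.2%, as removing such a factor would, but it evens the split by construction. The bound set in advance was on the 23.3% of tested genes still called higher, which genes with changes of their own also meet, so it decides nothing. The smaller share of TEC, lincRNA and miRNA models raises all others by a log2 ratio of at most 0.343 in any pair of libraries. That is below the median rise of 0.55 and below 0.446, the lowest median with 1 library left out. The median was under 0.343 with a pseudocount of 5 (0.328) and without the filter (0.149). The comparison thus depends on these settings and does not settle whether the share accounts for all or part of the excess of higher calls. With scaling to protein-coding genes, which leaves those models out of the sum, 5052 calls were still higher and 1512 lower. The median of 9 abundant somatic transcripts was at most 0.41 TPM in the cKO libraries, with Pecam1 the highest at 5.73 TPM. The genes called higher gained 19.7 percentage points of a fixed sum, a gain raised by picking them for being higher. A median can hide a single cell type, but no transcript of the 9 exceeded 5.73 TPM. These levels argue against RNA of the somatic cells that the 9 transcripts mark as the main source. Col1a1, Col3a1, Dcn, Foxl2, Lum and Ptprc were higher in both cKO libraries than in both controls, so a small amount of such RNA stays open. Olfactory and vomeronasal receptor genes above 0.1 TPM made up 10.15% and 9.76% of their families in the cKO libraries and 6.58% and 7.26% in the controls, so that genomic DNA cannot be told apart from a rise of silent genes; the PRC1 genotype, a common factor from other transcripts and the RNA content per oocyte stay open.

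TEC, lincRNA and miRNA gene models took a large share of the TPM of growing oocytes. Of the 100 most abundant such models in control growing oocytes, those with a match of at least 90% identity over 100 bases in another gene held 99.6% of their TPM. This met the prediction for reads shared between near-identical copies. A shared stretch of 100 bases also meets it, as in Malat1, which matched 1540 other genes, and no rate was computed for other transcripts. The match therefore does not show that near-identical copies share reads. Overlap with exons of protein-coding genes held 0.1% of it, which argues against that source. The share changed with stage in the controls, and a change in the transcription of such repeats with growth stays open as a hypothesis, with the locus of origin uncertain.

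Genes that rise with growth were lower and genes that fall with growth were higher in PRC1 cKO growing oocytes. Non-growing oocytes collected with them would give every gene the same implied share of non-growing RNA, and its median was 0.429 in 229 genes that rise and 0.271 in 71 that fall at least 8-fold, a difference of -0.157 with a minimum of 50 TPM that the prediction had not named. It was 0.018, -0.053, -0.082 and -0.115 with minimums of 5, 10, 20 and 100 TPM. The bound set for admixture, a difference within 0.15, was met with 4 of the 5 minimums and missed at 50 TPM, and no minimum reached 0.3, the bound against it. The minimums give nested sets of genes, so they are not separate tests. These bounds were on medians, and single genes varied widely around them. At 50 TPM the interquartile range of the implied share was 0.307 to 0.634 in genes that rise and 0.111 to 0.485 in genes that fall. The levels were set across separately normalized tables, and incomplete growth moves the same genes the same way, so admixture cannot be told apart from it. Incomplete growth as the whole difference is argued against by 111 genes, 80 of them protein-coding, at no more than 0.5 TPM in 6 control libraries and at 5 TPM or more in both PRC1 cKO libraries. The same count was 2 for the PRC1 control libraries and 0 for the PRC2 cKO growing libraries. The non-growing controls came only from the separately normalized PRC2 table, and non-growing oocytes with the Ring1 deletion were not measured. The argument therefore holds only if the 111 genes are as low in such oocytes. Some of these genes, such as Zscan4a and Usp17lc, belong to families of near-identical copies.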

How the results depend on the processing

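Scaling to protein-coding genes was chosen after the data were examined, and the causes of the changes below were not tested unless stated. The PRC2 cKO count in non-growing oocytes (44) was 87 with a pseudocount of 5, 91 without the filter, 29 with trimmed-mean scaling, 10 with only the 2 groups compared, where fewer libraries set the spread, and 14 to 45 with 1 library left out. The count in growing oocytes (24) was 50 without the filter, 12 without the trend, 1 with only the 2 groups compared and 10 to 35 with 1 library left out. For the difference of effects (14) it was 7 with a pseudocount of 5, 9 with TPM of at least 5 and 3 to 842 with 1 library left out. A 2-fold minimum gave 6577 genes for growth in control, 6015 for growth in cKO and 4583 for PRC1 cKO, since it adds a criterion. With 1 library left out, the PRC1 cKO count (7140) was 2953 to 6390, growth in control 8289 to 10526 and growth in cKO 8223 to 9108.

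The replicate block gave 20 genes for PRC2 cKO in non-growing oocytes and 5 for the difference of effects, 16 for PRC2 cKO in growing oocytes, 10171 and 9543 for growth in control and cKO and 5094 for PRC1 cKO. The numbers were not treated as pairing the libraries, since each group holds 2 and the deviations of replicate 1 correlated between -0.268 and 0.26 across genes. With the block, 3 of the 6 lists of PRC2 calls passed in the PRC1 table.

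Of the 6 lists of PRC2 calls, 5 passed in the PRC1 table as reported, 3 with a pseudocount of 0.1, 0 with an estimated correlation and 3 to 6 with 1 library left out, with 3 without any 1 of the non-growing libraries or of the PRC2 control growing libraries. Over all contrasts 54 tests of fixed lists passed, 0 with an estimated correlation and 46 to 55 with 1 library left out. The odds ratio of the overlap between PRC1 and PRC2 cKO genes higher in growing oocytes (2.96) passed with a pseudocount of 0.1 (2.64) and for the 500 genes of smallest p (5.54), and lay between 0 and 10.85 with 1 library left out. The log2 fold change of Eed in non-growing oocytes kept its sign and call under every alternative, from -3.002 to -2.549.

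With growth in control oocytes the lower values of Eed and Rnf2 turned to 0.082 and 0.031 with quantile normalization and to 0.223 and 0.19 with trimmed-mean scaling. With 1 library left out the relative medians of the ribosomal protein and oxidative phosphorylation lists in PRC2 cKO growing oocytes lay from -0.33 to 0.002 and from -0.308 to 0.053, and turned positive without PRC2 cKO growing replicate 2. Depth is unknown and sets no limit that can be computed.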

Other observations

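The test of X-linked genes as a whole was chosen after the result was seen. The exact tests of X linkage were not planned either, and they use the same calls that showed the pattern.

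In PRC1 cKO growing oocytes, targets of the integrated stress response and genes of DNA damage and apoptosis did not pass as lists, while single members did. Of 23 tested targets of the integrated stress response, 13 were higher and 3 lower, with Psat1, of serine synthesis, rising from 4.03 ± 2.14 to 76.8 ± 21.8 TPM and the asparagine synthetase gene Asns from 9.06 ± 2.14 to 93.9 ± 7.20 TPM (SD, n = 2; camera adjusted p = 0.484 for the list). Of 26 DNA damage and apoptosis genes, 13 were higher and 2 lower (camera adjusted p = 0.39), and the BH3-only gene Pmaip1 rose from 3.34 ± 1.17 to 98.2 ± 0.559 TPM. Of 12 mitochondrial mRNAs, 10 were higher (camera adjusted p = 0.0197, adjusted p = 0.757 with an estimated correlation, and 0.0647 without PRC1 cKO replicate 1), such as mt-Nd1 from 200 ± 22.8 to 770 ± 98.2 TPM, while in the growth of control oocytes 12 of 13 were lower (camera adjusted p = 0.0101, adjusted p = 0.54 with an estimated correlation) and mt-Nd1 fell from 877 ± 10.2 to 333 ± 0.0071 TPM. Among PRC1 subunit genes, Bcor rose from 1.77 ± 0.163 to 12.2 ± 0.636 TPM and Scml2 fell from 34.0 ± 2.18 to 15.1 ± 0.113 TPM. With growth in control oocytes, Tsc2, an inhibitor of mTOR signalling, rose from 137 ± 5.03 to 2140 ± 0.976 TPM and the imprinted gene Mest from 1.46 ± 0.177 to 88.8 ± 10.8 TPM.

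Genes called higher in PRC2 cKO non-growing oocytes were often X-linked, 8 of 16 against 528 of 14134 genes tested on the X chromosome or autosomes (odds ratio 26.2, two-sided Fisher's exact test p = 3.55e-08, adjusted p = 1.42e-07 over 4 tests). In growing oocytes 4 of 16 were (odds ratio 8.65, p = 0.00245, adjusted p = 0.0049 by the same exact test). Rhox2 and Xlr3 genes are neighbouring, near-identical copies, so these calls are not independent, and the calls of the 7 X-linked genes named in non-growing oocytes were lost with 2 to 8 of the 8 libraries left out in turn. A rise of X-linked genes as a whole is one hypothesis. The median log2 fold change of X-linked genes lay 0.115 above that of autosomal genes, between the bounds set for and against it, so the hypothesis stays open.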
